A study of mixed culture KAZ_0815 with 3 samples.

How the data were processed

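The series holds 3 RNA libraries of an undefined anaerobic community that, per the labels, includes a Smithella species, Methanosaeta concilii and Methanoculleus. Each library comes from 1 culture, grown at 30 °C on hexadecane (1.7 mmol), butyric acid (5 mM) or caprylic acid (2 mM). Per the labels' protocols, the hexadecane culture seeded both fatty acid cultures. It was harvested after 1146 days and the fatty acid cultures after 146 days, so carbon source and incubation time differ together in both comparisons with hexadecane. Total RNA was depleted of ribosomal RNA with a modified RiboZero kit, and libraries were made with a modified Nextera method, which fragments cDNA and adds adapters with a transposase, then sequenced on a MiSeq. The methods record no molecular identifiers, so copies of a fragment made by PCR count as separate reads.

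Bowtie 0.12.8, Cufflinks, HTSeq and DESeq are named in the submitters' processing notes, and the roles and the remaining versions are not given in the sources used here. For Smithella the authors deposited a pair of tables per fatty acid. The first kind holds read counts that the authors divided by DESeq size factors, a normalized signal on a scale of its own in each table, with the authors' fold ratio, log2 ratio and p-values, per the file headers. The other kind holds FPKM (nominally fragments scaled by transcript length and by the mapped total) with the authors' log2 ratio, p-value and q-value from Cufflinks, per the file headers. The FPKM of the same hexadecane library in the butyric acid table are 0.139 to 0.146 times those in the caprylic acid table. The scale is thus set per table, and a fixed minimum is stricter in the butyric acid table. For M. concilii the authors deposited FPKM tables of the Cufflinks kind, with locus coordinates on its chromosome. The table deposited for M. concilii on butyric acid is identical, byte for byte, to the one for caprylic acid and its header names caprylic acid, so no butyric acid value of M. concilii is reported here. Genome builds and annotations are not given in the sources used here.

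Of the values in the DESeq tables, 100% were whole multiples of the smallest value of their column, within 0.01 of a read, and reads per gene were recovered by dividing by that value. The hexadecane columns of both tables then held the same reads and differed by a single factor (0.395), which was used to put the butyric and caprylic acid values on a common scale. The hexadecane cell of smith_2776 is unreadable in the butyric acid table, so that gene was left out of that comparison. By the caprylic acid table it had 2512 reads in hexadecane, and it had 0 in butyric acid. It belongs to the hydrogenase and membrane electron transport lists. Their butyric acid medians and counts of higher and lower genes therefore lack a gene with a large loss, while their read shares include it. The authors' log2 ratio is listed as 0 for 1955 genes in the butyric acid table and 2112 in the caprylic acid table whose fold ratio is 0, so it was not used. In the FPKM table of M. concilii, low values of loci of at least 500 bp that hold 1 gene were whole multiples of a 1-fragment step after correction for length, with 33 of the hexadecane and 32 of the caprylic acid loci of up to 12 fragments within 0.1 of a whole number. The number of columns of other series was 0.

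Ratios were taken as log2((A + 1)/(B + 1)) on the authors' values, over genes with a mean of at least 10 in the 2 libraries compared, and a gene was called higher or lower when the ratio was at least 2-fold. With 1 library per carbon source there are no replicates, no p-value was computed and a count model could not be fitted on the recovered reads. Intervals of ratios and of shares are 95% exact Clopper-Pearson intervals on reads. These intervals and the floor of 3 reads per library for a gene or list without reads cover counting error only. A fold against a gene without reads was computed against that floor and is written as "at least"; it takes the reads of the other library as counted, so the 95% limit of the ratio lies nearer to 1. The log2 ratio of such a gene is set by the pseudocount and is no bound, so list medians are also given with such genes at their bound. The rules for lists, named genes, filter and size were fixed before the data were examined. The 17 Smithella lists were matched on product names, and a list's median was ranked among 10000 random lists of the same size matched on mean expression in 10 bins, as a description of these libraries. That mean includes the fatty acid library, so the matching depends in part on the values compared. Random lists draw genes singly, while neighbouring genes, which some lists hold, shared read counts more often than independent reads would (last part). Both kinds of rank can therefore be too extreme. The number of members with reads was ranked in the same way, matched on hexadecane reads; this rank does not use the pseudocount and was chosen after the data were seen. Named genes are the 8 highest and 8 lowest ratios of each comparison with hexadecane among genes with a product other than hypothetical, the 3 members of each list with the highest mean, the 5 genes with the most reads per library and the 5 largest differences in each direction between the fatty acids. The text gives examples from that set. The corresponding M. concilii lists were left out because the product names of some loci do not go with the locus lengths.

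The authors' scaling and equal totals differ. Scaling the Smithella libraries to equal totals of reads raises log2 ratios against hexadecane, before the pseudocount, by 1.17 for butyric acid and 1.23 for caprylic acid. Ratios of genes without reads hardly move, so the median over genes stays at -5.56 for butyric acid and goes from -6.91 to -6.90 for caprylic acid. Other pseudocounts, filters, scalings, a 4-fold rule, other thresholds for the authors' q-values and the Cufflinks tables were tried as alternatives. The size rule and the list ranking were tested on simulated counts with 200 genes changed by 4-fold. At the butyric acid depth the rule recovered 100% of the raised and 87.7% of the lowered genes past the filter and called 14.6% of the unchanged genes. At the caprylic acid depth it recovered 100% of both and called 1.70% of the unchanged ones. The counts were drawn from the hexadecane profile, which at these depths leaves about 9.73% and 1.45% of genes without reads. In the real libraries 1963 and 2120 of 2753 genes had none, so these rates do not carry over to the calls below. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.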

Results

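RNA libraries of a methanogenic community were compared between hexadecane, a liquid alkane of crude oil, and a pair of fatty acids, butyric acid and caprylic acid (octanoic acid), which are shorter-chain substrates. There was 1 library per carbon source, so no difference below has a replicate check. Of 2753 Smithella genes, 2744 had reads in the hexadecane library, 790 in the butyric acid library and 633 in the caprylic acid library. The reads on these genes summed to 1718593, 16634 and 102347. The median gene had 511 reads in hexadecane and 0 in each fatty acid library. In the caprylic acid library the 50 genes with the most reads held 33.4% of the total, in the butyric acid library 25.3% and in the hexadecane library 8.58%. Reads were found in both fatty acid libraries for 252 genes and in neither for 1582. In hexadecane 89.2% of 1375 Smithella genes of above-median effective length lay within 2-fold of their median FPKM, against 41.5% of the 520 with reads in butyric acid and 27.9% of the 438 with reads in caprylic acid. Reads from DNA are not excluded in the hexadecane library, to which both fatty acids are compared. For M. concilii the median long single-gene locus held about 841 fragments in hexadecane and 188 in caprylic acid.

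**Figure D1:**
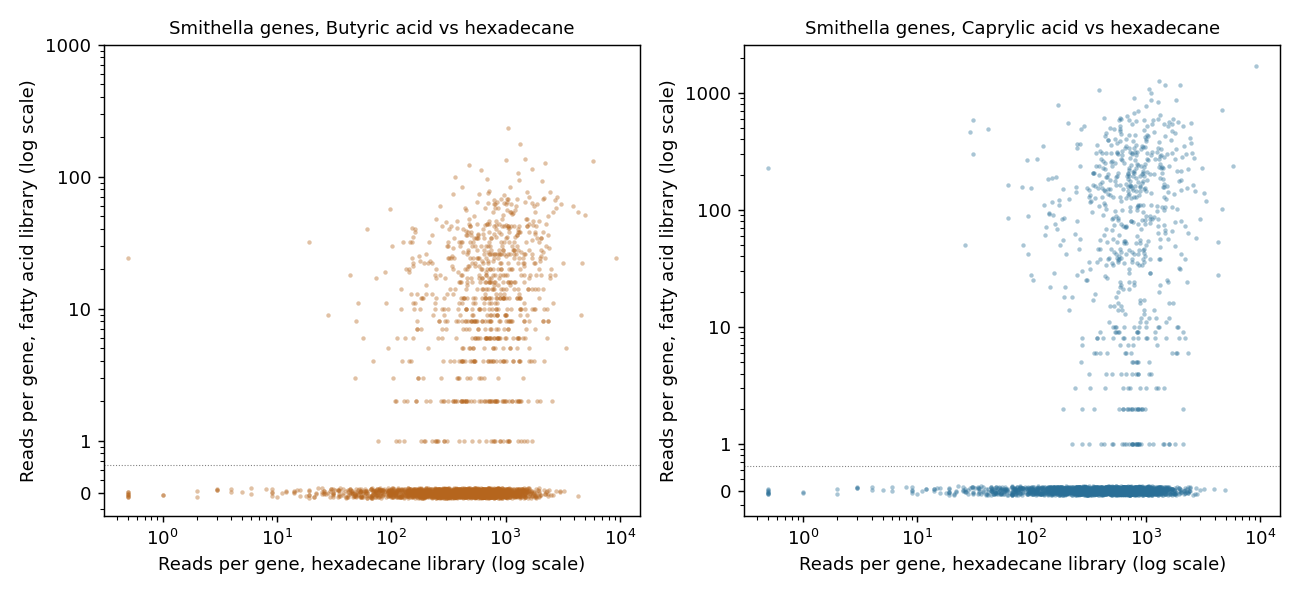
Reads per Smithella gene in the butyric acid (left) and caprylic acid (right) library against the hexadecane library, on log axes with genes without reads placed at the line marked 0; each point is a gene. In the butyric acid panel 1963 genes and in the caprylic acid panel 2120 genes lie at 0.

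The comparison of butyric acid with hexadecane asks which Smithella genes differ in reads when the community is fed a short fatty acid in place of the alkane. Genes of beta-oxidation, the stepwise shortening of acyl-CoA chains, carried 4.49% of the reads in butyric acid (95% interval 4.18 to 4.82) against 1.62% in hexadecane (1.60 to 1.64), and without smith_365, the member with the most reads, 3.09% (2.83 to 3.36) against 1.56% (1.54 to 1.58). The acyl-CoA dehydrogenase smith_365 had the most reads of any gene in the butyric acid library, 233, and was 10.1-fold higher than in hexadecane (log2 ratio 3.32, counting interval 3.12 to 3.54). The electron transfer flavoprotein beta subunit smith_479, a carrier that takes electrons from acyl-CoA dehydrogenases, was 8.45-fold higher (log2 ratio 3.06, interval 2.78 to 3.37). The ATP synthase B chain smith_11 was 9.72-fold higher and the pyrophosphate-energized proton pump smith_584, which couples pyrophosphate cleavage to proton export, 6.02-fold higher. Past the filter were 2439 genes, of which 190 were higher, 1905 lower and 344 between, and 1650 of the lower genes had no reads in butyric acid. Through the pseudocount, a gene without reads can be called lower in butyric acid though its bound is under 2-fold. The methylmalonyl-CoA gene smith_1232 is an example, at least 1.40-fold lower. How many of the 1650 reach 2-fold at the bound was not counted, here or in the lists below. In the values from Cufflinks 643 genes passed the filter, 341 higher and 249 lower, and among the 788 genes with reads in both libraries 189 were higher and 255 lower. Both of these choices select genes by their butyric acid value, so neither gives a direction: 364 of the 643 genes passed only through butyric acid, and 62.2% had reads there against 28.7% of all genes. Over the 2439 genes the Cufflinks values gave 380 higher and 1742 lower. With the median log2 ratio centred at 0 the split became 829 higher and 616 lower, but that median belongs to genes without reads and is set by the pseudocount (-8.86, -5.56 and -2.55 at pseudocounts of 0.1, 1 and 10), so this split gives no direction. Centred on the median of those 788 genes, -0.18, the split was 223 higher and 1879 lower. That small median leaves the values close to the authors' scaling, so this split is no independent check of it.

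Among the 34 beta-oxidation genes past the filter 4 were higher, 15 lower and 15 between. The list's median log2 ratio of -0.75 lay at the 99.3 percentile of matched random lists, and its 21 members with reads at the 99.85 percentile. Both ranks are given in this order for each list below, since the rank of a median depends on genes without reads. The acyl-CoA dehydrogenases smith_2602 and smith_2627 were 2.95-fold and 2.79-fold higher. Of the 4 electron transfer flavoprotein genes 2 were higher, with a median of 0.76 (percentiles 94.8 and 97.6). The alpha subunit smith_1736 was 2.86-fold higher, and smith_1737, the beta subunit numbered next to it, had no reads against 393 in hexadecane, at least 2.86-fold lower. The alpha subunit smith_480, numbered next to the raised beta subunit smith_479, had a log2 ratio of 0.02 (interval -0.94 to 0.84). For 25 fatty acid activation and CoA transfer genes, which load acids onto CoA, the numbers were 0 higher and 21 lower. Their median was -5.53, or -1.98 with genes without reads at their bound (percentiles 6.14 and 15.0). The long-chain-fatty-acid--CoA ligases smith_1911 and smith_2046 had log2 ratios of 0.63 and 0.36. Among 11 genes matched for alkane activation and glycyl radical enzymes 1 was higher and 7 lower, with a median of -6.25, or -2.00 at the bound (percentiles 7.91 and 52.7). They held 1.09% of the reads against 0.818%, and without smith_2381 0.679% (0.560 to 0.816) against 0.691% (0.679 to 0.703). None of these 11 is named as an alkylsuccinate synthase: the product names are those of pyruvate formate-lyases, formate C-acetyltransferase and their activating enzymes. Sequences were not examined, so an alkylsuccinate synthase listed under such a name is not excluded. The formate C-acetyltransferase smith_2381 had a log2 ratio of 0.53 and the activating enzyme smith_2252 was 2.31-fold higher.

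The list for formate dehydrogenases, which interconvert formate and carbon dioxide, had a median of -0.32 over 7 genes (percentiles 96.8 and 91.4), with 2 higher and 3 lower. In the values from Cufflinks the median over the same 7 genes was 0.99. The median of -0.32 is the ratio of smith_767, named as the formation protein FdhE and not as a subunit of the enzyme. The alpha subunit smith_1439, listed with 0 reads in hexadecane, had 24 in butyric acid, at least 367-fold higher. Its q-value in the authors' deposited table from Cufflinks was 0.480. In hexadecane 9 of 2753 genes had no reads, and the gamma subunit smith_1442 had 922. Why smith_1439 is listed at 0 there was not tested. The hydrogenase list, which includes the nickel incorporation protein HypB (smith_131), had 0 of 8 genes higher and 6 lower (median -4.82, at the bound -1.17, percentiles 93.0 and 81.2). Its HoxF subunit smith_2379 had a log2 ratio of 0.75. ATP synthase genes had 3 of 18 higher and 12 lower (median -4.49, at the bound -1.17, percentiles 96.9 and 92.0), among them smith_116, an alpha chain, 2.12-fold higher. Membrane electron transport had 3 of 16 genes higher and 12 lower (median -5.01, at the bound -1.27, percentiles 78.2 and 64.3). The c-type cytochrome biogenesis protein smith_2292 was 10.4-fold higher and the NADH dehydrogenase smith_948 2.96-fold higher. Of 3 methylmalonyl-CoA genes 0 were higher and 2 lower (median -4.88, at the bound -0.49, percentiles 58.4 and 64.2). Of 10 genes matched for the TCA cycle 0 were higher and 8 lower (median -6.06, at the bound -1.79, percentiles 54.7 and 42.1). They include smith_346, a 3-isopropylmalate dehydrogenase matched on part of its name, which held 14 of the list's 28 reads in butyric acid. The aconitate hydratase smith_1999 was at least 10.5-fold lower.

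Chaperones and proteases had 1 of 16 genes higher and 15 lower (median -6.06, at the bound -1.70, percentiles 12.5 and 25.8), and the higher one, the small heat shock protein smith_766, was 11.6-fold higher. Oxidative stress genes had 2 of 13 higher and 10 lower (median -5.53, at the bound -1.15, percentiles 67.1 and 47.9): the rubrerythrin smith_148 was 6.90-fold and the catalase smith_557 3.36-fold higher. Ribosomal proteins had 3 of 37 higher and 32 lower (median -5.25, at the bound -0.95, percentiles 90.2 and 28.2), with the large-subunit protein L10p, smith_2449, 2.76-fold higher. The median at the bound is under 2-fold, so part of the 32 were called lower only through the pseudocount. The small-subunit protein S1p, smith_874, was at least 14.4-fold lower. Flagella, pili and chemotaxis had 0 of 18 higher and 15 lower (median -6.47, at the bound -2.54, percentiles 16.5 and 52.3). Transporters had 6 of 73 higher and 48 lower (median -5.31, at the bound -1.82, percentiles 85.0 and 97.2), and mobile elements and CRISPR genes 2 of 23 higher and 15 lower (median -4.57, at the bound -1.26, percentiles 73.3 and 88.2). The list meant for stable RNA matched no rRNA or tRNA gene but enzymes that act on them, of which 1 of 5 was higher and 4 lower (median -6.63, at the bound -2.27, percentiles 12.1 and 29.3). Outside the lists, the glycosyl transferase smith_2216 was 77.2-fold higher, from 19 reads in hexadecane and 32 in butyric acid. The TetR regulator smith_2571 was 12.7-fold and the LacI regulator smith_739 13.5-fold higher. The lowest were a mobile element protein, smith_2195, at least 31.2-fold lower, and the glycosyl transferase smith_609, at least 23.7-fold lower.

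In the authors' deposited table from Cufflinks 2 genes had a q-value under 0.05 for butyric acid against hexadecane, both higher: smith_2216 (q = 0.0184) and smith_151 (q = 0.0129), a hypothetical protein. The authors' deposited table from DESeq gave 4 genes an unadjusted p under 0.05, of which 4 had no reads in butyric acid, and no adjusted value. These tests compare the reads of 2 libraries, not the conditions.

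**Figure D2:**
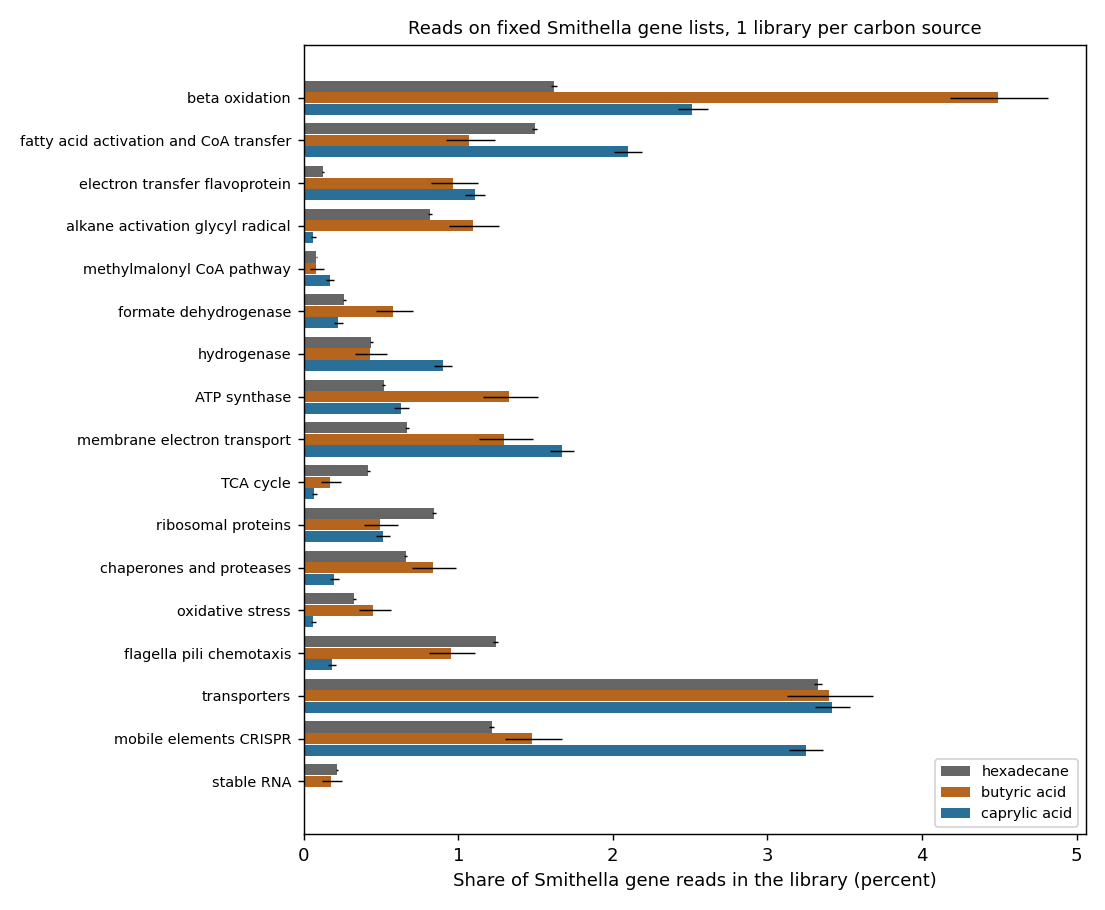
Share of the reads on Smithella genes that fell on each of 17 fixed gene lists, in percent, for the 1 library of each carbon source; error bars are 95% Clopper-Pearson intervals, which cover counting error only. Beta-oxidation held 1.62%, 4.49% and 2.51% of the reads in hexadecane, butyric acid and caprylic acid, and the list labelled alkane activation glycyl radical 0.818%, 1.09% and 0.0625%.

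Caprylic acid, a fatty acid of medium chain length, was compared with hexadecane in the same way. The acyl-CoA dehydrogenase smith_365 was again among the genes with the most reads and was 7.20-fold higher than in hexadecane (log2 ratio 2.84, interval 2.72 to 2.97). Electron transfer flavoprotein held 1.11% of the reads (1.04 to 1.17) against 0.124% in hexadecane (0.118 to 0.129), almost entirely through the beta subunit smith_1737, 19.1-fold higher (log2 ratio 4.25, interval 4.09 to 4.43). The heterodisulfide reductase cytochrome subunit smith_1819 was 5.17-fold higher. The genes matched for glycyl radical enzymes held 0.0625% of the reads (0.0482 to 0.0798) against 0.818% (0.805 to 0.832). Past the filter were 2636 genes, with 191 higher, 2249 lower and 196 between, and 2003 of the lower genes had no reads in caprylic acid. The values from Cufflinks gave 418 higher and 2049 lower of 2556 genes. Among the 632 genes with reads in both libraries, which are selected by their caprylic acid value, 190 were higher and 246 lower. Centring the median log2 ratio at 0 gave 882 higher and 683 lower, again by a median that the pseudocount sets (-10.21, -6.91 and -3.82), and centring on those 632 genes (-0.23) gave 223 higher and 2230 lower.

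Of 35 beta-oxidation genes 3 were higher, 29 lower and 3 between (median -7.80, at the bound -4.79, percentiles 15.4 and 46.2), although the list's share of reads was 2.51% (2.42 to 2.61) against 1.62%. That excess rests on smith_365: without it the share was 1.47% (1.40 to 1.55) against 1.56% (1.54 to 1.58). The 3 higher genes included the short-chain acyl-CoA dehydrogenase smith_1415, 2.46-fold, and smith_2602, 2.91-fold. Fatty acid activation had 4 of 25 genes higher and 16 lower (median -6.62, at the bound -3.63, percentiles 46.7 and 85.5). Its long-chain-fatty-acid--CoA ligase smith_2342 was 3.41-fold higher. The acetyl-coenzyme A synthetase smith_831, which forms acetyl-CoA from acetate and is not matched by the list, was 6.45-fold higher. Of the 4 electron transfer flavoprotein genes 1 was higher and 2 lower (median -3.82, at the bound -2.32, percentiles 86.6 and 86.7), and smith_479 had no reads, at least 28.6-fold lower. The 11 genes matched for glycyl radical enzymes were all lower under the authors' scaling (median -8.35, at the bound -5.35, percentiles 0.06 and 2.40), 10 of them without reads. The pyruvate formate-lyase smith_656, the one with reads, had a log2 ratio of -2.36, which was 0.19 in the values from Cufflinks. The lyase smith_2253 was at least 110-fold lower.

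Membrane electron transport had 3 of 20 genes higher and 14 lower, and its median of -4.00 (at the bound -1.76) lay at the 99.99 percentile and its members with reads at the 99.8 percentile. In the values from Cufflinks the median was -1.82 over the same 20 genes and 1.11 over the 17 that passed the filter there. The formate dehydrogenase list had 1 of 7 genes higher and 6 lower (median -7.94, at the bound -4.93, percentiles 29.9 and 26.3). The higher one was smith_1439 with 227 reads, at least 541-fold higher, with a q-value of 0.355 in the authors' deposited table from Cufflinks. The hydrogenase list had 1 of 9 higher and 7 lower (median -6.62, at the bound -3.60, percentiles 56.8 and 72.9), the F420-reducing beta subunit smith_1660 being 3.10-fold higher. For HoxF, smith_2379, the log2 ratio was -1.17 and turned to 0.059 with equal totals. ATP synthase genes had 1 of 19 higher and 16 lower (median -7.04, at the bound -4.18, percentiles 35.9 and 58.1), the higher one being the alpha chain smith_10, 4.39-fold. The methylmalonyl-CoA genes had 0 of 3 higher and 2 lower (median -6.19, at the bound -3.17, percentiles 59.4 and 69.6). Of the genes matched for the TCA cycle 0 of 10 were higher and 10 lower (median -7.93, at the bound -4.92, percentiles 51.8 and 31.6).

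Mobile elements and CRISPR genes had 5 of 23 genes higher and 16 lower (median -5.65, at the bound -3.34, percentiles 80.2 and 99.8). Genes named only as mobile element protein are not matched by this list. Among them smith_2195 and smith_2458 had log2 ratios of -3.49 and -1.77. The Mu-like prophage protein smith_2834 was 8.07-fold and the CRISPR helicase Cas3, smith_2106, 3.34-fold higher. Transporters had 2 of 79 higher and 70 lower (median -7.40, at the bound -4.46, percentiles 37.2 and 46.2): the RND efflux transporter smith_683 was 4.18-fold and the mechanosensitive channel smith_2305 5.63-fold higher. Ribosomal proteins had 3 of 42 higher and 37 lower (median -6.48, at the bound -3.46, percentiles 69.1 and 32.8), with L18p, smith_650, 20.8-fold higher. Chaperones and proteases had 1 of 18 higher and 17 lower (median -7.30, at the bound -4.54, percentiles 52.3 and 24.2). Oxidative stress genes had 0 of 15 higher and 14 lower (median -6.85, at the bound -3.83, percentiles 57.6 and 15.9). In the list of flagella, pili and chemotaxis 0 of 19 were higher and 19 lower (median -7.97, at the bound -4.96, percentiles 46.0 and 40.4), including the methyltransferase CheR, smith_2748, at least 127-fold lower. The 7 enzymes of the list meant for stable RNA had no reads in caprylic acid, which allows a share of up to 0.00293% (median -7.72, at the bound -4.71, percentiles 13.7 and 8.68). Outside the lists, the glycosyl transferase smith_2210 was 114-fold, the pyrimidine-nucleoside phosphorylase smith_532 33.0-fold and the dihydroxy-acid dehydratase smith_2176, of branched-chain amino acid synthesis, 6.85-fold higher. The lowest gene was the cyclic glucan synthase smith_603, at least 231-fold lower. In the authors' deposited table from Cufflinks 0 Smithella genes had a q-value under 0.05, the smallest being 0.0781 for smith_2034, and their DESeq table gave 4 genes an unadjusted p under 0.05.

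Caprylic acid was also compared directly with butyric acid, with the tables aligned on their shared hexadecane library. Incubation time was the same and concentration differed. Of 998 genes past the filter 367 were higher in caprylic acid, 557 lower and 74 between. No reads in butyric acid were found for 287 of the higher genes and none in caprylic acid for 465 of the lower ones. Some of the 287 are not shown to be 2-fold higher, such as smith_563, at least 1.25-fold higher. The electron transfer flavoprotein beta subunits split between the libraries: smith_1737 was at least 54.7-fold higher in caprylic acid, and smith_479 at least 241-fold higher in butyric acid. The alpha subunit smith_1736, numbered next to smith_1737, was lower in caprylic acid (log2 ratio -1.48, interval -2.07 to -0.88). The acyltransferase smith_185 (at least 60.2-fold), the acetyl-coenzyme A synthetase smith_831 (at least 52.3-fold) and the helicase Cas3, smith_2106 (at least 44.9-fold), were higher in caprylic acid. In butyric acid the small heat shock protein smith_766 was at least 260-fold and the TetR regulator smith_2571 at least 213-fold higher. With the median centred at 0 the split was 482 higher and 427 lower, where the pseudocount sets the median (-4.13, and -1.89 at a pseudocount of 10), and centred on genes with reads in both it was 374 and 553.

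Across 2433 genes past the filter in both comparisons, the log2 ratios of butyric and caprylic acid against the shared hexadecane library correlated with a Pearson r of 0.0802 (Spearman 0.220), against 0.0182 in 100 simulations with counting noise and no change. The covariance was 0.809 against a simulated 0.00514. Genes are not independent replicates. A gene without reads in either fatty acid library takes both ratios from the shared hexadecane library and the pseudocount. The simulation leaves genes without reads by counting noise only, so the excess is not read as a shared response. Higher in both were 19 genes, where independent lists would share 13.2, and lower in both were 1632, where they would share 1618. The acyl-CoA dehydrogenases smith_365 and smith_2602 and the cytochrome biogenesis protein smith_2292 are among the 19. Between the authors' DESeq and Cufflinks tables, the log2 ratios of genes with values above 0 in both libraries correlated across genes with r of 0.971 over 758 genes for butyric acid and 0.993 over 607 for caprylic acid. The Cufflinks ratios were higher by a median of 1.28 and 2.68 log2 units, so 73.9% and 72.0% of these genes had the same direction in both tables.

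For M. concilii, a methanogen that splits acetate into methane and carbon dioxide, caprylic acid was compared with hexadecane over 2888 genes at 2525 distinct loci in FPKM. The authors list locus positions on the M. concilii chromosome. Some of the listed product names do not go with the lengths of their loci, so identifiers and positions are given. Of 2744 genes past the filter 588 were higher, 666 lower and 1490 between, and 220 of the lower genes were listed at 0 in caprylic acid. Scaled to equal totals the split was 209 higher and 1177 lower. A q-value under 0.05 was given in the authors' deposited table to 3 genes. Both higher ones, cds289 (positions 293191 to 296025) and cds828 (838503 to 841364), are listed without a product. Neither is known here to code for protein, so their rise is not read as gene regulation. They stood at 1210 and 1193 FPKM in hexadecane and 37529 and 37327 FPKM in caprylic acid (q = 2.93e-06 for each). The lower one, cds1008 (1019870 to 1021180), stood at 953 and 2.44 FPKM (q = 0.0378). The middle 50% of long single-gene loci lay between 241 and 415 FPKM in hexadecane and between 165 and 511 FPKM in caprylic acid, and 81.2% and 61.1% of them within 2-fold of the median.

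**Figure D3:**
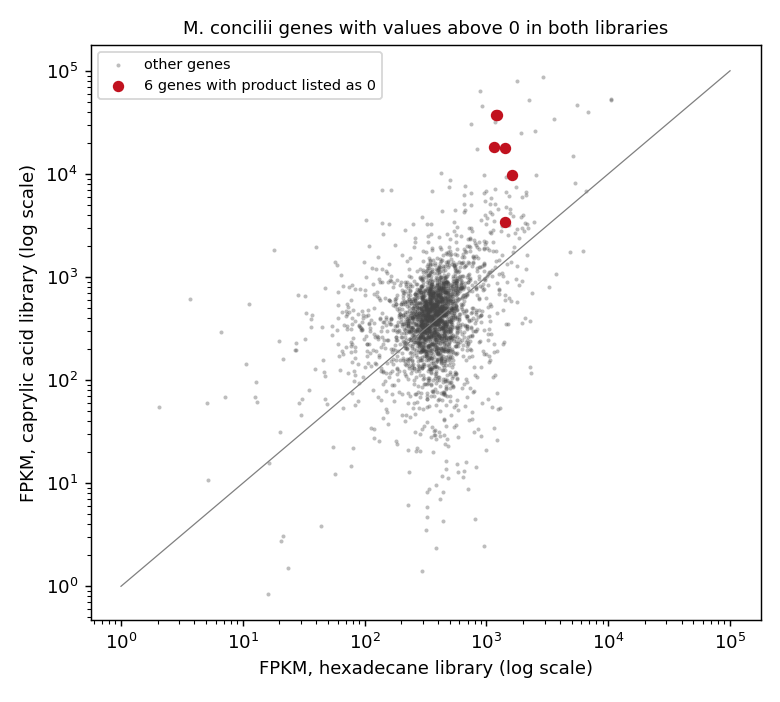
FPKM of M. concilii genes in the caprylic acid library against the hexadecane library, on log axes, for genes above 0 in both; each point is a gene, the line marks equal values, and 6 genes listed with 0 as product are in red. The red points include cds289 and cds828 at 37529 and 37327 FPKM in caprylic acid.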

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

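The 6 M. concilii loci whose product is listed as 0 belong to no gene list and drew attention because they took 23.2% of the FPKM times length over single-gene loci in caprylic acid against 1.66% in hexadecane. They lie in 2 clusters, each with a locus of 1468 bp followed by one of 2835 or 2862 bp and a short one of 216 or 116 bp. Their FPKM in caprylic acid was 17959 and 18149 for the 1468 bp loci, and 3442 and 9727 for the short ones. Without a product it is not known whether they code for protein or for ribosomal RNA that escaped depletion, which was not tested. Their rise in caprylic acid is therefore not read as gene regulation.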

How the results depend on the processing

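Tests of genes with reads in both libraries, centring on those genes, totals without the 6 unnamed loci, shares without a list's most-read member and filters without the fatty acid value were chosen after the data were seen. No carbon source has a second library, so no result could be checked by leaving a library out, and No paired analysis was possible because each group holds 1 sample. For M. concilii on butyric acid, its comparison with caprylic acid, the shared response and all its lists no alternative gives a value. For butyric acid against hexadecane in Smithella (190 higher, 1905 lower), a mean of at least 50 left 745 lower, centring gave 829 higher and 616 lower, equal totals 393 higher, a 4-fold rule 69 higher, the values from Cufflinks 341 higher and 249 lower, those of the genes past the main filter 380 higher, 115 higher at a hexadecane value of at least 50, and genes with reads in both libraries 255 lower. For caprylic acid (191 and 2249), centring gave 882 higher and 683 lower, equal totals 316 higher, a 4-fold rule 88 higher, the values from Cufflinks 418 higher, those of the genes past the main filter 417 higher, and genes with reads in both libraries 246 lower. Stricter filters and the 4-fold rule leave fewer genes by construction. For M. concilii (588 and 666), equal totals gave 209 higher and 1177 lower, equal totals without the 6 unnamed loci 225 and 1114, and the 4-fold rule 193 and 414. Between the fatty acids a mean of at least 50 left 311 lower. The authors' calls for Smithella were 0 at q under 0.01 for butyric acid and 1 at q under 0.1 for caprylic acid. The other pseudocounts moved none of these counts by over 1.5 times.

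Centring turned the sign of 11 of 17 list medians for butyric acid and 8 of 17 for caprylic acid, pseudocount 10 of 0. A mean of at least 50 turned 4 of 16 for butyric acid (beta-oxidation, formate dehydrogenase, ATP synthase, membrane electron transport) and 0 of 16 for caprylic acid. The Cufflinks table turned 6 of the 7 medians it gave for butyric acid (beta-oxidation, ATP synthase, membrane electron transport, oxidative stress, transporters, mobile elements) and 1 of 17 for caprylic acid (membrane electron transport). For butyric acid both select genes by their butyric acid value (55.8% and 62.2% of genes kept had reads, 28.7% of all), so these turns carry no direction. Over the genes past the main filter the Cufflinks values turned 1 of 17 (formate dehydrogenase, 0.99) and 0 of 17, and a hexadecane value of at least 50 turned 0 of 16 and 0 of 17. Leaving out the member with the most reads in the fatty acid, a choice that leans to lower ratios, turned the ratio of read shares to hexadecane for butyric acid in glycyl radical enzymes (0.983), chaperones (0.162), oxidative stress (0.582) and transporters (0.926), and for caprylic acid in beta-oxidation (0.944), electron transfer flavoprotein (0.795), methylmalonyl-CoA (0), ATP synthase (0.424) and transporters (0.708). Signs of 12 of 67 named genes for butyric acid changed with centring, 7 with equal totals and 8 with the Cufflinks table, and of 64 for caprylic acid 8, 4 and 4. Among these, the genes at least 2-fold in the main setting were for butyric acid, with centring, smith_599 (4.29), smith_839 (3.93), smith_1232 (0.68), smith_1995 (1.22) and smith_2140 (3.88), and with the Cufflinks table smith_253 (-5.26). For caprylic acid they were, with centring, smith_116 (2.73), smith_563 (3.74), smith_656 (4.56), smith_1232 (0.72) and smith_2379 (5.75), with equal totals smith_2379 (0.059), and with the Cufflinks table smith_656 (0.19) and smith_2379 (0.47). Centring adds the same amount to every gene, and the pseudocount sets that amount because the median gene has no reads, so its turns carry no direction; for other turns of named genes the cause was not tested. Centring on genes with reads in both libraries moved no count by over 1.5 times.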

Other observations

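All tests in this part were chosen after the results were seen. In Smithella, 1963 genes had no reads in butyric acid and 2120 in caprylic acid. Lower depth with an unchanged profile was argued against: the hexadecane profile thinned to each total would leave 268 and 39.9 genes without reads. That profile is nearly level, and lower depth with a more uneven profile was not tested. Few starting fragments copied many times may account for part of the genes without reads. Neighbouring genes held equal read counts in 12.7% of 276 pairs in butyric acid and 12.2% of 189 pairs in caprylic acid, 35 and 23 pairs. In 1000 draws of independent reads at each gene's own level at most 19 and 11 pairs were equal. A response to the carbon source stays open and cannot be told apart from library quality with 1 library per condition. Reads in both fatty acid libraries were found for 252 genes, where 227 (209 to 246 in 95% of permutations) were expected at their hexadecane levels. If fragments were copied in this way, counting intervals of the fatty acid libraries would be too narrow; the number of molecules was not measured.

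In hexadecane, values were nearly level across genes. Within 2-fold of the median lay 81.2% of 1529 long M. concilii loci, against 61.1% in caprylic acid, and 89.2% of 1375 Smithella genes of above-median effective length. Reads from DNA rather than RNA could give such a profile, as could a culture with even, low expression after 1146 days. With over 90% taken as the mark of the first and under 70% as excluding it, both values fall between, so these cannot be told apart, and incubation time and carbon source differ together.

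The M. concilii product names may be out of step with their loci. Of 26 loci under 100 bp, the size of a transfer RNA gene, 26 carry a protein name, and the last 75 identifiers have none. A candidate explanation is that names numbered by protein gene were joined to identifiers that number all genes. With the offset set on a part of 22 protein families of known length, 76.2% of 21 held-out names fell on a locus of usual length (16 names), against 42.9% as listed (9 names). This missed the 80% taken as the mark of the explanation, so it stays open.

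In the hexadecane library 306 of 2888 M. concilii genes lay under 0.25 times the median FPKM. The next gene was also that low for 62.4% of them, against 10.6% of all genes, and 75.8% of them were under that mark in caprylic acid too, against 18.7% of all genes.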
